A study of Mus musculus with 8 samples.

How the data were processed

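RNA of TEC71 cells, an immortalized mouse medullary thymic epithelial line, was hybridized to 8 single-colour Agilent SurePrint G3 mouse arrays of the 8x60K format, per the labels. The groups, per the labels, were a control with Cas9 nickase and one guide RNA (3 arrays), Gtf2i knock-in clone 1 (3 arrays) and knock-in clone 3 (2 arrays). The deposited values are processed signals, a background-corrected fluorescence intensity on a linear scale, made with Agilent Feature Extraction 11.5.11 per the submitters' processing notes. How the cultures behind replicates were separated is not given in the sources used here. All 8 arrays come from 1 slide and 1 scan time, with the 3 controls and the first clone 1 array in row 1 of the slide and the others in row 2.

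Each array holds 62976 spots, of which 3671 are control spots and 59305 carry 56605 distinct probes. Spots marked as non-uniform or as population outliers, 114 to 242 per array, were left out. Signals were converted to log2, reduced by the 75th percentile of the array and averaged over the spots of a probe. Probes were named through their transcript accession and the RefSeq names of GRCm38.p6, which gave 32994 probes a gene symbol. The other 23611 probes were kept under their accession as unnamed transcripts. File headers name an older build, so no coordinates are given. A gene with several probes was represented by the brightest probe over all arrays. A gene was tested where its probe was well above background on every array of at least 1 group, which kept 25353 genes and unnamed transcripts, 14719 of them with a symbol.

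Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes, two-sided, Benjamini-Hochberg over all tested, threshold 0.05) in one fit of the 3 groups, so that the 2 clone 3 arrays borrow the spread of the others. Residual degrees of freedom were 5 and prior degrees of freedom 3.38. Knock-in against control was a separate fit of 2 groups. A gene counts as changed in both clones where it passed against the control in each clone with the same sign. Because both comparisons share the controls, 100 simulations with unchanged clones gave the correlation and overlap that sharing alone makes. Where a group was at background on every array, the fold is given as a lower limit. Each value of that group was set to no less than the lowest log2 signal called well above background on its array. That lowest signal ran from -5.448 to -4.564 between arrays, so the limits are approximate. Where only part of a group's arrays were above background, the fitted fold is given.

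The 41 gene lists and the rule for naming genes were written before the data were examined, as were the tests of the comparisons and the alternatives, apart from those named as added. Lists with at least 5 tested members were tested on the mean of the clones with camera at its preset correlation of 0.01, Benjamini-Hochberg over lists, beside camera with an estimated correlation and fry. The text names Gtf2i, Gtf2ird1, Gtf2ird2 and Ptgs2. It also names the 12 higher and the 12 lower genes with the largest smaller fold of both clones among those above background on all 8 arrays, and the 6 switched on and the 6 switched off with the largest lower limit. Up to 4 passing members of each list, members of lists with 5 or fewer passing, up to 6 genes each way between the clones, and genes with opposite signs follow. Genes without a standard symbol were not named, and some genes that the rule selects are not reported here. Genes outside this rule are marked as chosen after their values were seen, except where a list with a called shift needed its members of the other direction named.

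Alternatives were normexp background correction with offset 50, quantile and median scaling, no filter and a filter on all 8 arrays, the mean of all probes, a variance trend with robust estimation, array weights (statmod 1.5.0 and limma), the array row as a block, other thresholds, other designs, each array left out in turn, and the other set tests. Normexp used the median signal of the spot, since the mean signal is not among the columns. A block for slide or scan could not be formed. Fits within a single row, with genes that carry a symbol only, or without the X and Y chromosomes were added after the results were seen, as were the tests of the array row and of the X chromosome and the scan of gene families.

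The fit was tested on simulated data with 100 changed genes per size among 25353. Values were drawn independently for each gene from a normal distribution with its residual spread. At a change of 1 log2 it recovered 60% in clone 1, 42% in clone 3, 72% in the knock-in fit and 42% in both clones, and at 0.5 log2 it recovered 1%, 1%, 19% and 0%. False calls numbered 1, 0, 10 and 0. So few changed genes make the adjusted threshold stricter than in the real fits, where 31.1% passed in clone 1. The recovery rates therefore do not describe the real comparisons. Camera recovered a list shifted by -0.5 log2 and called 0 of the 40 others. Simulated genes were not correlated, so this does not test the preset correlation on real lists. Tables were read with jsonlite 2.0.0 and the package data.table (version 1.17.8), and figures were drawn with matplotlib 3.10.9, pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15.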

Results

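Gene expression was measured with 1-colour microarrays in TEC71, a line of immortalized epithelial cells from the mouse thymic medulla. Thymic epithelium forms the tissue in which T cells mature. Gtf2i encodes TFII-I, a transcription factor that also takes part in signalling. A point mutation had been placed in Gtf2i with a Cas9 nickase, and 2 edited clones were hybridized, clone 1 on 3 arrays and clone 3 on 2 arrays. The 3 control arrays carried RNA of cells that had received the nickase with one guide RNA. Between 55.3% and 59.3% of the 56605 probes were well above background on an array, and the 75th percentile of the processed signal lay between 268 and 377. No spot was saturated. The number of arrays limits the precision of every value below, and levels are log2 signals relative to the 75th percentile of the array.

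Gtf2i, the edited gene, was measured first. Its level was 4.41 ± 0.05 in the controls (SD, n = 3), 3.96 ± 0.07 in clone 1 (SD, n = 3) and 3.82 ± 0.03 in clone 3 (SD, n = 2). The level fell by 0.46 log2 in clone 1 (SE 0.10, adjusted p = 0.0075) and by 0.59 log2 in clone 3 (SE 0.11, adjusted p = 0.0042). A probe level does not read a point mutation, so this value checks nothing about the edit. The other Gtf2i probes gave differences of -0.45 and -0.25 log2 in clone 1 and of -0.46 and -0.42 log2 in clone 3. With the row of the array on the slide as a block the mean of the clones was -0.501 log2 and no longer passed (adjusted p = 0.0787). Within the row that holds the controls, the single clone 1 array lay at -0.44 log2. That array, on which every value within row 1 rests, had a brightest spike-in signal of 2797 where the other arrays had 17164 to 30390.

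Gtf2ird1 and Gtf2ird2, the relatives of Gtf2i beside it on chromosome 5, behaved differently from each other. Gtf2ird2 rose by 0.69 log2 in clone 1 (SE 0.10, adjusted p = 0.0015) and by 0.77 log2 in clone 3 (SE 0.12, adjusted p = 0.0017), from 1.47 ± 0.11 in the controls (SD, n = 3). Its call in clone 3 ended with the row as a block (adjusted p = 0.066). Gtf2ird1 did not differ in clone 1 (-0.12 log2, adjusted p = 0.46) or in clone 3 (-0.01 log2, adjusted p = 0.96). Ptgs2, which encodes the inducible cyclooxygenase, rose by 0.81 log2 in clone 1 (SE 0.17, adjusted p = 0.0081) but did not pass in clone 3 (0.35 log2, SE 0.19, adjusted p = 0.21). The difference between the clones did not pass for Ptgs2 (-0.45 log2, adjusted p = 0.45), and its call in clone 1 ended with the row as a block (adjusted p = 0.102).

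The comparison of each clone with the nickase control asks which transcripts differ in cells that carry the mutation. Ccl2, which encodes a chemokine for monocytes, fell from 3.24 ± 0.05 in the controls (SD, n = 3) to -3.14 ± 0.11 in clone 1 (SD, n = 3) and -3.63 ± 0.01 in clone 3 (SD, n = 2), which is 83.6-fold and 117-fold. Complement C3 fell 20.5-fold in clone 1 and 26.5-fold in clone 3, from 5.05 ± 0.08 in the controls. Cxcl5, a chemokine for neutrophils, fell 18.6-fold and 37.2-fold from 6.56 ± 0.15. Il1a, which encodes interleukin 1 alpha, went from 1.99 ± 0.12 in the controls to background on every knock-in array, a fall of at least 121-fold in clone 1 and at least 116-fold in clone 3. The surface antigen gene Ly6a fell by 6.23 log2 in clone 1 (SE 0.14) and by 5.83 log2 in clone 3 (SE 0.16).

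Further genes that stayed above background on all 8 arrays fell by over 4 log2 in both clones. Cd93, which encodes a membrane glycoprotein, fell by 4.18 and 4.21 log2. The matricellular gene Ccn4 fell by 4.27 log2 in clone 1 and 4.43 log2 in clone 3, and Slc43a3, a nucleobase carrier, fell by 5.25 and 5.11 log2. Tnni2, which encodes a troponin of fast muscle, fell by 5.08 and 4.77 log2. Syt8 of the synaptotagmin family (-5.26 and -5.14 log2) and Baiap2l1, which shapes actin-rich membranes (-4.96 and -5.18 log2), completed the set. The probes of Ly6c1 (-6.16 and -5.59 log2) and Ly6c2 (-5.98 and -5.54 log2) may read each other's transcript, as may those of Rhox4a and Rhox4g. Another Ly6c1 probe, above background on all 8 arrays, gave smaller falls of -3.37 and -3.00 log2. Transcripts lost to background in both clones also included the homeobox gene Irx1 (at least 64.8-fold and 62.1-fold), the differentiation inhibitor Eid2 (at least 59.4-fold and 56.9-fold) and the beta-1 adrenergic receptor Adrb1 (at least 39.5-fold and 37.8-fold). For Rhox4g the lower limits were 48.5-fold and 46.5-fold, and for Rhox4a 46.6-fold and 44.6-fold.

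Among the genes named here Vldlr, a lipoprotein receptor, had the largest lower limit of a rise. It was above background on none of the control arrays and rose to 3.35 ± 0.08 in clone 1 (SD, n = 3) and 3.10 ± 0.13 in clone 3 (SD, n = 2), at least 312-fold and 263-fold. Nt5e, the ectonucleotidase that makes adenosine outside the cell, rose 38.6-fold in clone 1 and 36.1-fold in clone 3 from -3.59 ± 0.12 in the controls (SD, n = 3). Aebp1, a secreted matrix protein gene, rose by 5.30 log2 (SE 0.10) and 5.01 log2 (SE 0.11). Ctsh, which encodes a lysosomal protease, rose by 4.47 log2 (SE 0.11) and 4.48 log2 (SE 0.13). The adhesion molecule gene Alcam rose by 4.52 log2 (SE 0.24) and 4.44 log2 (SE 0.27), and the adhesion gene Mpzl2 by 5.05 and 5.01 log2. Grem1, which encodes a secreted BMP antagonist, rose at least 39.0-fold and 22.3-fold, and Elovl4, an elongase of very long fatty acids, at least 24.1-fold and 22.4-fold.

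Other genes among the largest rises fell into several classes of function. Membrane carriers and receptors were represented by Slc6a13, a GABA transporter (4.43 and 4.88 log2), and by the adhesion receptor Adgrg6 (4.67 and 4.38 log2). The carboxypeptidase gene Cpm rose by 4.38 and 4.42 log2, the LIM-domain gene Fhl1 by 4.47 and 4.40 log2, and Cgref1, which encodes a calcium-binding secreted protein, by 4.66 and 4.63 log2. Flywch2, of the FLYWCH family, rose by 4.96 and 5.09 log2 and the X-linked homeobox gene Rhox5 by 5.55 and 4.89 log2. Arhgap44, which acts on small GTPases, rose at least 21.5-fold and 20.7-fold, Sfmbt2, a Polycomb-group gene, at least 20.9-fold and 20.4-fold, and Lemd1 at least 15.5-fold and 18.9-fold from background.

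Limma's test passed 7896 of 25353 genes and unnamed transcripts in clone 1 (31.1%), 3716 higher and 4180 lower. In clone 3 it passed 7669 (30.25%), 3362 higher and 4307 lower. Changes of at least 2-fold were made by 1110 higher and 1112 lower transcripts in clone 1 and by 1086 higher and 1533 lower in clone 3. Scaled by the median of each array, 3622 were higher and 3448 lower in clone 1, and 3687 higher and 3343 lower in clone 3, so which direction holds more transcripts depends on the scaling. These p-values measure the spread among these arrays, since the labels do not say whether replicates were separate cultures. With the array row as a block 4349 passed in clone 1 and 2068 in clone 3, and with row 1 alone, which holds the controls and 1 array of clone 1, 3597 passed.

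Both clones shared most of these changes. In both, 2862 transcripts rose and 3090 fell, among them 911 and 917 by at least 2-fold in each clone, and 4044 of the 5952 carried a gene symbol. With median scaling 2898 rose and 2399 fell. Only Nts and an unnamed transcript passed in both with opposite signs. Log2 fold changes of the clones correlated at r = 0.924 across transcripts, which are not independent replicates. Both comparisons use the same 3 controls, and simulated clones without any change gave r = 0.447 and 0 shared calls on average. Their covariance averaged 0.0211 where 0.540 was observed. Independent sets would share 492.8 higher and 710.1 lower transcripts. With 3 controls no separate control sets of 2 arrays could be made. The simulated covariance argues against noise of the shared arrays as the main source, although a small part may come from it. With the array row as a block 1967 transcripts passed in both, 1849 of them shared with the fit without it. Of the 187 named genes called in both clones, 125 kept both calls with that block and all 187 kept their sign. The clone 1 array in the row of the controls shared every sign, but with that block clone 1 rests on this array alone. These are therefore 1 check, on genes chosen with that array in the fit.

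**Figure D1:**
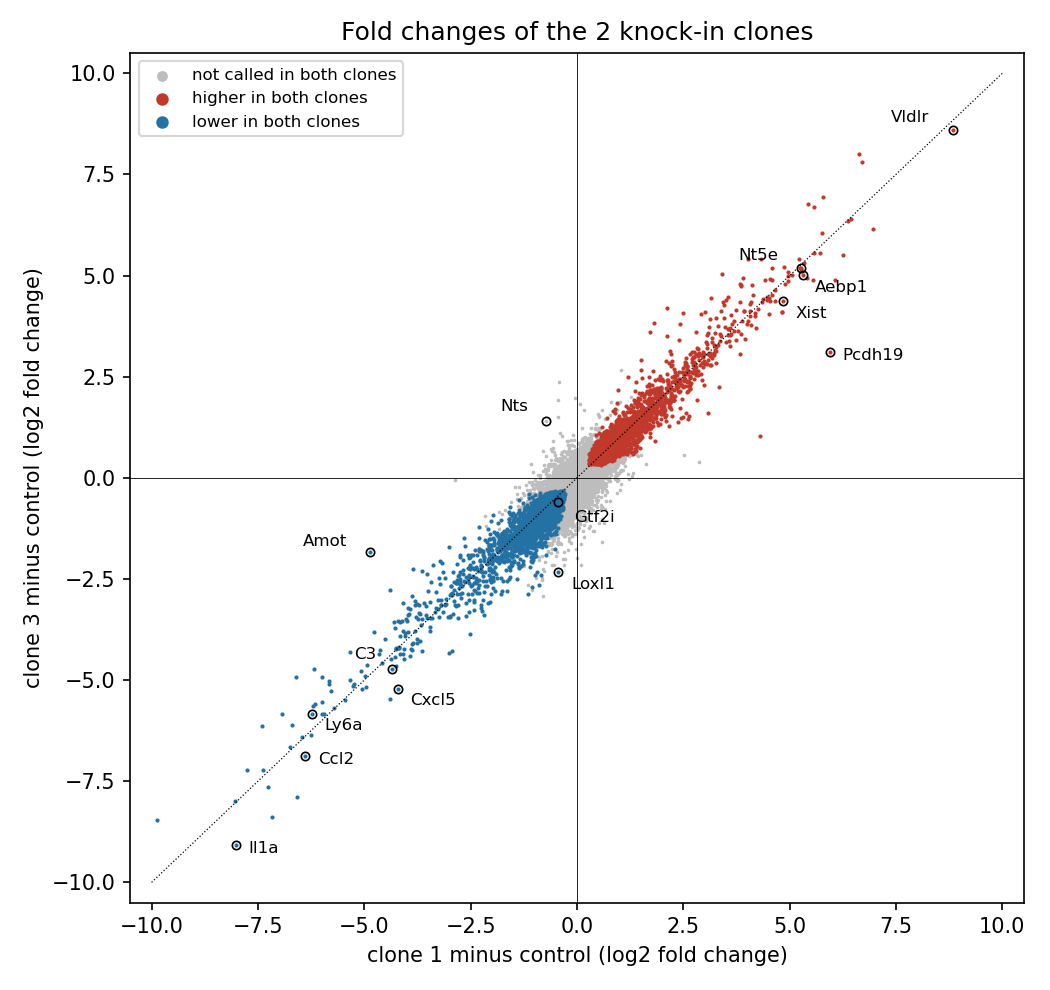
Log2 fold change against the control in clone 1 (horizontal axis) and clone 3 (vertical axis) for each of the 25353 genes and unnamed transcripts tested, with the 2862 higher in both clones in red and the 3090 lower in both in blue. The points follow the dotted line of equal change, apart from a few such as Nts, Loxl1, Amot and Pcdh19 (Amot, Pcdh19 and Xist were chosen after their values were seen).

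A fit of 2 groups compared all knock-in arrays with the controls, with the difference between clones left in the spread. It counts every array as a replicate, although several arrays come from the same clone. Its p-values therefore do not measure the spread among clones of a genotype. Ccl2, Ly6a and Il1a were lower and Vldlr, Nt5e and Aebp1 higher in each of the 5 knock-in arrays than in any control. These genes were chosen for their large changes in both clones on the same arrays, so this separation followed from the choice. The 5 knock-in arrays differed from the 3 controls in 8818 transcripts, 4057 higher and 4761 lower, of which 1092 and 1195 changed by at least 2-fold. With the row as a block 4322 passed. Arrays of the same group correlated at 0.993 to 0.995, arrays of different clones at 0.989 to 0.994, and control with knock-in arrays at 0.964 to 0.97.

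**Figure D2:**
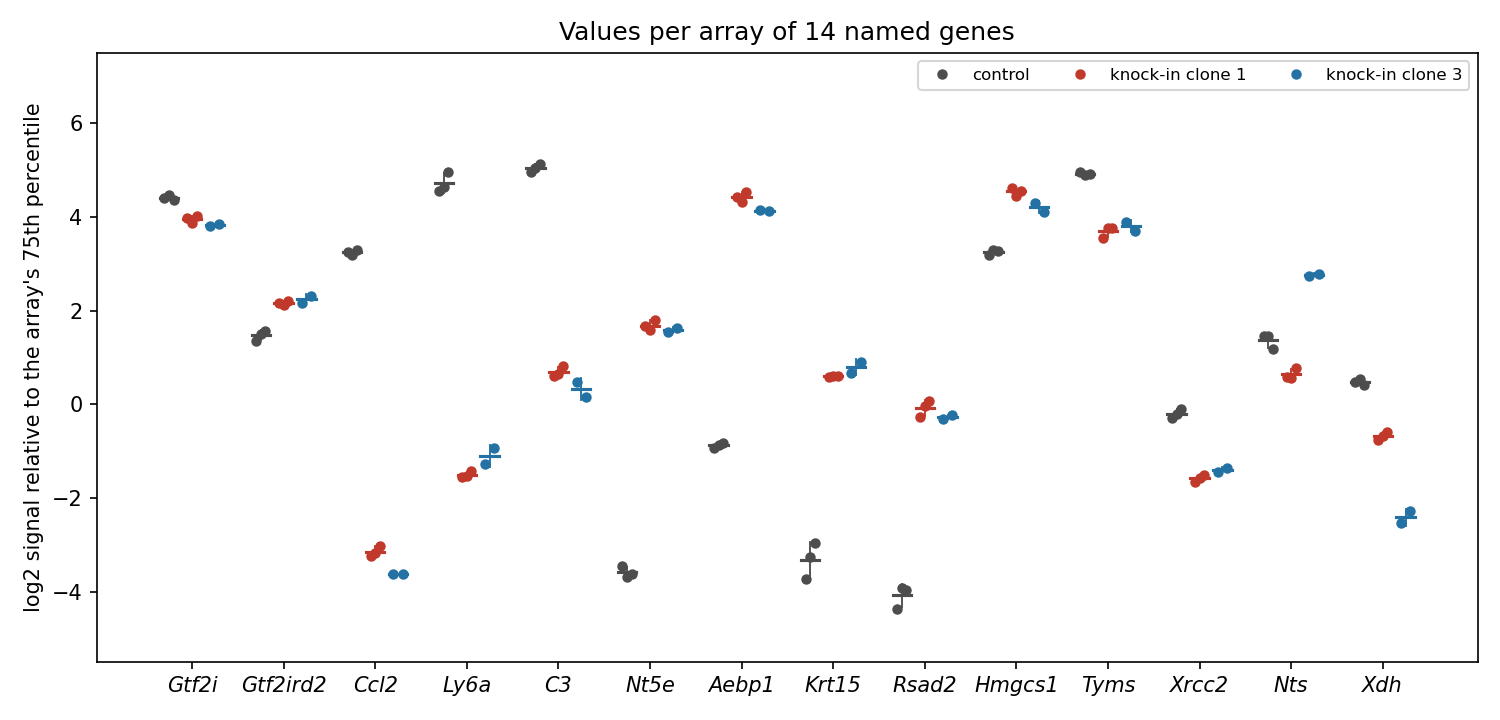
Log2 signal relative to the 75th percentile of the array for 14 named genes, with each point an array (3 control, 3 clone 1, 2 clone 3), each bar a group mean and each vertical line its SD. Ccl2 lies at 3.24 in the controls and at -3.14 and -3.63 in the clones, whereas Nts lies at 0.64 in clone 1 and at 2.77 in clone 3.

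Genes were then read by fixed lists of pathway members and markers. Of the 14719 tested genes with a symbol, 4044 passed in both clones, so changed members by themselves do not set a list apart. Genes for DNA replication and entry into S phase were lower. Tyms, which makes thymidylate, fell by 1.22 log2 in clone 1 (SE 0.11, n = 3) and by 1.13 log2 in clone 3 (SE 0.12, n = 2), and the transcription factor gene E2f2 fell by 1.09 log2 (SE 0.14) and 0.96 log2 (SE 0.16). Replication factor Cdc45 fell by 1.02 and 0.62 log2 and polymerase subunit Pold1 by 0.85 and 0.73 log2. Of 36 members of the list 14 fell, 1 rose (the cyclin gene Ccnd3) and 21 did not pass in both clones, with the same counts when adjusted over the list alone. Camera with its preset correlation called the list lower (adjusted p = 4.71e-04, adjusted p = 0.224 with an estimated correlation), at a median of -0.42 log2. By clone the median was -0.58 log2 in clone 1 and -0.26 log2 in clone 3. For the mean of the clones it was -0.45 log2 with the row as a block. In the row 1 array of clone 1 it was -0.58 log2. The calls of E2f2, Cdc45 and Pold1 in clone 3 ended with that block.

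DNA repair genes moved in the same direction. Xrcc2, which acts in homologous recombination, fell by 1.38 log2 in clone 1 (SE 0.10, n = 3) and 1.20 log2 in clone 3 (SE 0.12, n = 2). The exonuclease gene Exo1 fell by 1.14 log2 (SE 0.12) and 0.74 log2 (SE 0.14), and Rad54l by 1.01 and 0.80 log2. Of 40 members 15 fell, 1 rose (H2ax) and 24 did not pass in both clones, as when adjusted over the list alone. Camera called the list lower (adjusted p = 4.71e-04, adjusted p = 0.224 with an estimated correlation), with a median of -0.40 log2, -0.43 log2 with the row as a block and -0.47 log2 in the row 1 array of clone 1. Exo1 (adjusted p = 0.0501) and Rad54l lost their calls in clone 3 with that block. By clone the list median was -0.48 log2 in clone 1 and -0.33 log2 in clone 3.

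Cholesterol synthesis genes were higher. Dhcr7, which makes the last step to cholesterol, rose by 1.5 log2 in clone 1 (SE 0.13, n = 3) and by 1.35 log2 in clone 3 (SE 0.14, n = 2). Hmgcs1, which acts early in the pathway, rose by 1.30 log2 (SE 0.11) and 0.97 log2 (SE 0.12), Hsd17b7 by 1.14 log2 (SE 0.13) and 1.03 log2 (SE 0.14), and Fdft1, the squalene synthase gene, by 1.01 log2 (SE 0.20) and 0.88 log2 (SE 0.22). Of 23 members 9 rose, 0 fell and 14 did not pass in both clones, as when adjusted over the list alone. By clone, 15 rose and 0 fell in clone 1, and 9 rose and 3 fell in clone 3. Camera called the list higher (adjusted p = 0.00115, adjusted p = 0.224 with an estimated correlation), with a median of 0.33 log2, 0.36 log2 with the row as a block and 0.41 log2 in the row 1 array of clone 1. With that block Hsd17b7 and Fdft1 lost their calls in clone 3. By clone the list median was 0.46 log2 in clone 1 and 0.24 log2 in clone 3.

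More interferon-induced genes rose than fell. The antiviral gene Rsad2 rose by 4.0 log2 in clone 1 (SE 0.15, n = 3) and 3.81 log2 in clone 3 (SE 0.17, n = 2) from -4.08 ± 0.25 in the controls (SD, n = 3). Ifit1, which binds foreign RNA, rose by 3.09 log2 (SE 0.25) and 2.90 log2 (SE 0.28), and Ifi44 rose from background at least 7.07-fold and 5.64-fold. Cmpk2, a nucleotide kinase gene beside Rsad2, rose by 2.52 and 2.58 log2. The RNA sensor gene Dhx58 and the guanylate-binding genes Gbp2, Gbp3 and Gbp4 belong to the list too but fell. Of 35 members 17 rose, 4 fell and 14 did not pass in both clones, and 18 rose and 5 fell when adjusted over the list alone. Camera called the list higher (adjusted p = 0.00983, adjusted p = 0.224 with an estimated correlation), with a median of 0.44 log2, 0.38 log2 with the row as a block and 0.35 log2 in the row 1 array of clone 1. Cmpk2 lost its call in clone 3 with that block. By clone the list median was 0.49 log2 in clone 1 and 0.39 log2 in clone 3.

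In the list of ATF4 and unfolded protein response genes, the chaperone gene Hyou1 rose by 0.78 log2 in clone 1 (SE 0.12, n = 3) and 0.64 log2 in clone 3 (SE 0.14, n = 2), and the stress factor gene Ddit3 by 0.65 log2 (SE 0.12) and 0.75 log2 (SE 0.14). Creld2 and Sdf2l1, which act in the endoplasmic reticulum and were chosen after their values were seen, also rose. The stress gene Nupr1 fell by 1.28 and 1.57 log2. Vldlr is the fifth riser among the 25 members, 19 of which did not pass in both clones, and it is a receptor that other regulators control as well. The counts were the same when adjusted over the list alone. By clone the list median was 0.25 log2 in clone 1 and 0.16 log2 in clone 3. Camera called the list higher (adjusted p = 0.0108, adjusted p = 0.224 with an estimated correlation), with a median of 0.18 log2 but a mean of 0.51 log2. Vldlr, with a fitted rise of 8.84 and 8.60 log2 from background, raises this mean, and the list was not tested without it. The call ended with the row as a block (adjusted p = 0.154, median 0.12 log2) and in row 1 (adjusted p = 0.0956, median 0.17 log2), and Hyou1 and Ddit3 lost theirs in clone 3 with that block.

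These were the 5 of 41 lists that camera called, and each was also called in either clone alone. With an estimated correlation between genes 0 lists passed, and 7 had an unadjusted p under the threshold. The 36 lists that follow were not called on the mean of the clones. In clone 1 alone camera also called the mitosis list (adjusted p = 0.00803) and the serine and one-carbon list (adjusted p = 0.0101) lower. In clone 3 alone it called keratins, p53 targets and immediate early genes higher and fibroblast markers lower, each at an adjusted p of 0.0452. With an estimated correlation 0 lists passed in either clone, the lowest adjusted p being 0.142 in clone 1 and 0.246 in clone 3. The counts of their members are given for both clones together, in the order higher, then lower.

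**Figure D3:**
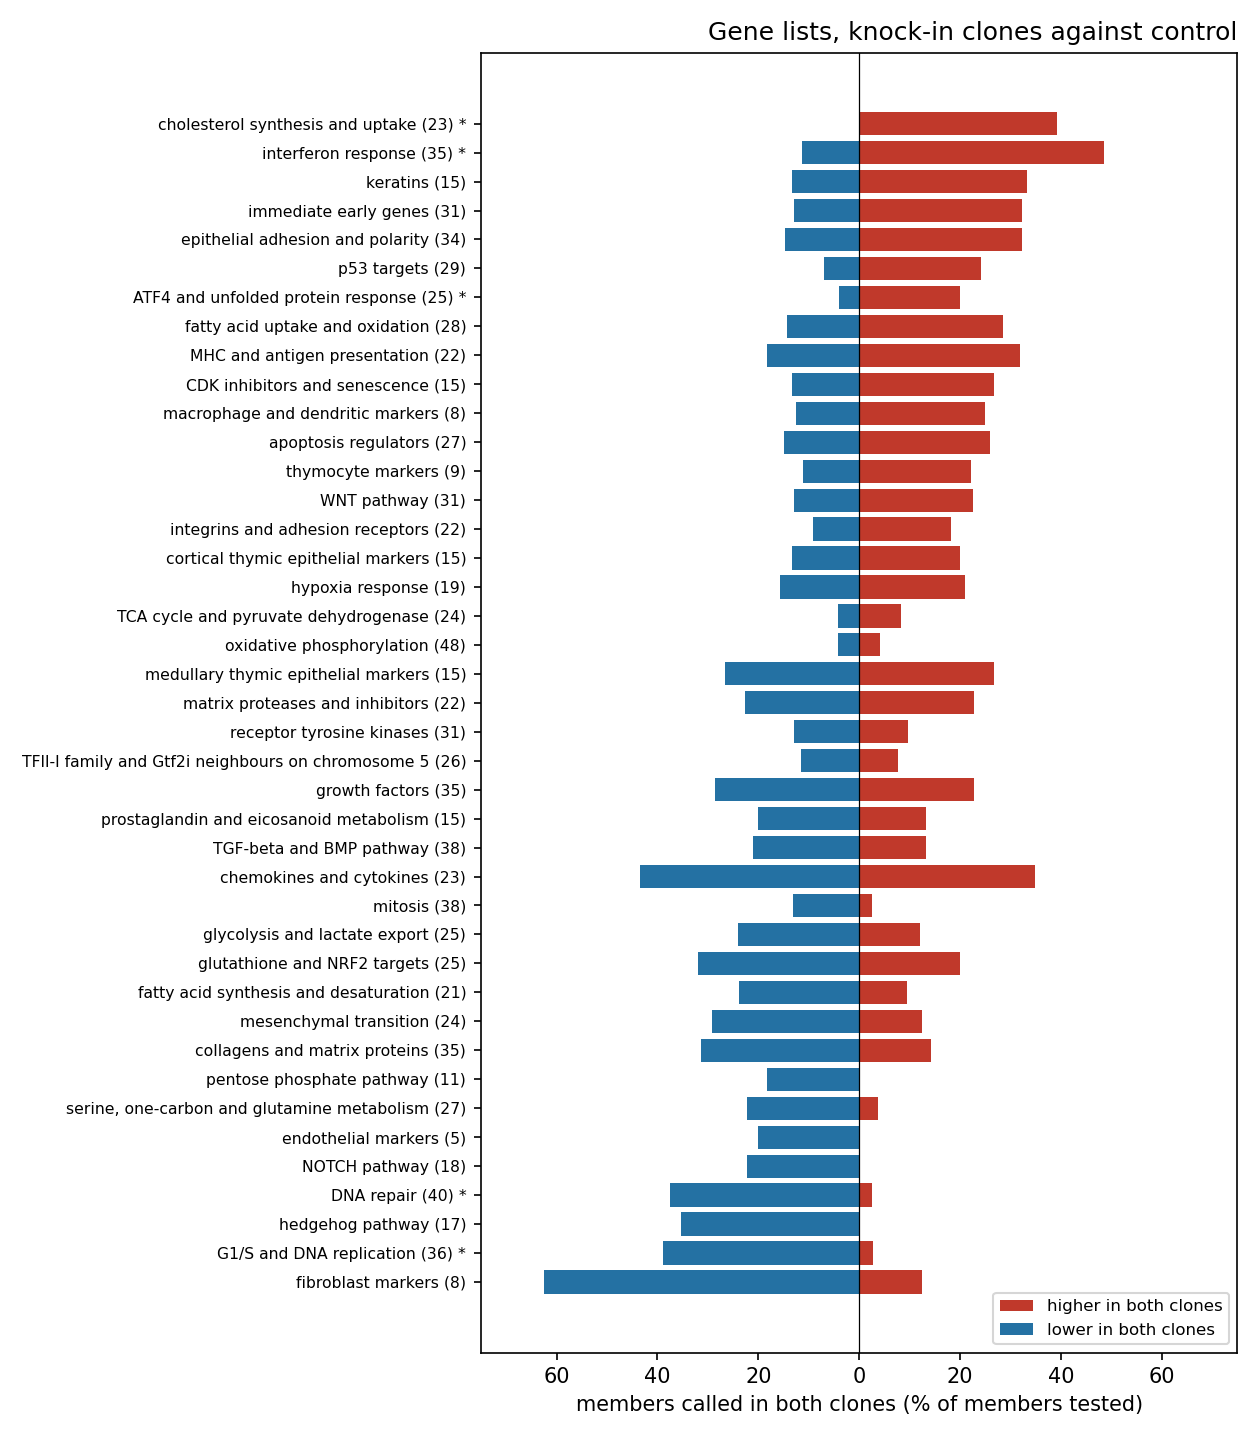
Share of the tested members of each of the 41 lists (number tested in brackets) that was higher (red, to the right) or lower (blue, to the left) in both clones, in percent of members tested, with an asterisk at the 5 lists called by camera with its preset correlation. Cholesterol genes had 9 of 23 members higher and 0 lower, whereas G1/S genes had 14 of 36 lower and 1 higher.

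Some epithelial genes changed strongly. The keratin gene Krt15 rose by 3.92 log2 in clone 1 (SE 0.18, n = 3) and 4.11 log2 in clone 3 (SE 0.20, n = 2), Krt17 rose by 2.18 and 2.23 log2, Krt10 rose by 1.29 and 1.49 log2, and Krt5, of basal epithelium, fell by 1.32 and 1.13 log2. Of 15 keratin genes 5 rose and 2 fell, in the list alone as well (adjusted p = 0.0664). St14, which encodes the membrane protease matriptase, rose by 4.35 log2 in either clone, the tight junction gene Tjp3 rose by 1.73 and 2.08 log2, and the claudin gene Cldn6 fell by 5.83 and 5.02 log2. Among 34 genes of adhesion and polarity 11 rose and 5 fell, 13 and 5 in the list alone (adjusted p = 0.0664). Markers of medullary epithelium went both ways (4 and 4 of 15, adjusted p = 0.955), with Spink5 higher by at least 3.48-fold and 3.50-fold and Avil by 1.51 and 1.30 log2. The members that fell were Krt5, Cd80, Ltbr and Relb, with Ltbr and Relb chosen after their values were seen. Of 15 markers of cortical epithelium 3 rose and 2 fell (adjusted p = 0.756). The median of the medullary list was -0.05 log2 where its mean, like the test, was positive (0.02 log2).

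Matrix and mesenchymal genes went both ways. Col12a1, a fibril-associated collagen gene, rose at least 23.3-fold in clone 1 and 13.8-fold in clone 3 by its brightest probe, whereas another probe, above background on all 8 arrays, gave 0.97 and 0.63 log2. Thbs2, a matricellular gene, rose by 2.57 log2 (SE 0.15) and 2.73 log2 (SE 0.17). Of 35 collagens and matrix proteins 5 rose and 11 fell (adjusted p = 0.666), and their median of -0.20 log2 and the downward test stand against a mean of 0.11 log2. Fibroblast markers, a list that shares genes with the collagens, were lower for 5 of 8 members and higher for Cd34, chosen after its values were seen (median -0.98 log2, adjusted p = 0.0525). Fbln1 fell by 2.46 and 2.66 log2 and Pdgfra by 1.30 and 1.83 log2. Of 24 mesenchymal genes 3 rose and 7 fell, 3 and 8 in the list alone (adjusted p = 0.616), with the intermediate filament gene Vim lower by 1.16 and 1.30 log2 and Snai1 by 2.51 and 1.97 log2. Matrix proteases split evenly (5 and 5 of 22, adjusted p = 0.955, mean -0.13 log2 against an upward test), with the urokinase gene Plau lower by 2.02 log2 in either clone and Adam19 by 2.11 and 2.68 log2. Of 22 integrins and adhesion receptors 4 rose and 2 fell (adjusted p = 0.81), with Itga7 higher by 3.32 and 3.29 log2 and a median of -0.05 log2 against a mean of 0.28 log2 and an upward test.

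Every signalling list held members that passed in both clones, and none had a called shift on the mean of the clones. With 4044 of 14719 genes with a symbol passing in both clones, changed members are to be found in most lists. Hedgehog genes fell in 6 of 17 cases and rose in 0 (adjusted p = 0.0664), among them the effectors Gli2 (-3.53 and -2.37 log2) and Gli1 (-1.06 and -0.92 log2). NOTCH genes fell in 4 of 18 cases and rose in 0 (adjusted p = 0.069), with the ligand genes Jag1 (-1.11 and -1.27 log2) and Dll1 (-1.19 and -1.41 log2) and the receptor gene Notch2 (-0.98 and -1.15 log2) all lower. In the WNT list 7 of 31 rose and 4 fell (adjusted p = 0.5), with Wnt6 higher by at least 8.67-fold and 6.86-fold and Rnf43, which removes WNT receptors, lower by 3.00 log2 and by at least 12.1-fold. In the TGF-beta and BMP list 5 of 38 rose and 8 fell, 7 and 9 in the list alone (adjusted p = 0.955). Bmp4 rose by 4.09 log2 (SE 0.13) and 3.77 log2 (SE 0.14), and its other probe gave 3.14 and 3.03 log2. Of 31 receptor tyrosine kinases 3 rose and 4 fell (adjusted p = 0.955, mean -0.03 log2 against an upward test), with Epha1 up by 1.64 and 1.68 log2. Of 35 growth factors 8 rose and 10 fell, 9 and 11 in the list alone (adjusted p = 0.955, mean -0.02 log2 against an upward test), with Vegfc, of lymphatic growth, lower by 3.80 and 3.04 log2. Of 31 immediate early genes 10 rose and 4 fell, 11 and 4 in the list alone (adjusted p = 0.0664), with the phosphatase gene Dusp1 up by 2.66 and 2.51 log2.

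Immune genes other than the interferon list were divided. Among 23 chemokines and cytokines 8 rose and 10 fell (adjusted p = 0.853, median -0.02 and mean -0.85 log2), and Ccl20 fell by 4.40 log2 in clone 1 and at least 24.5-fold in clone 3. Members that rose, chosen after their values were seen, included Ccl5, Cxcl10, Il11 and Il18. Among 22 genes of antigen presentation 7 rose and 4 fell (adjusted p = 0.0664). H2-DMb1, which loads peptides onto MHC class II, rose by 3.61 and 3.71 log2, the class I gene H2-D1 rose by 1.03 and 1.09 log2, and the costimulatory gene Cd80 fell by 2.31 and 2.86 log2. Of 8 macrophage and dendritic markers Cd68 and Cd74 rose and Lyz1 fell (adjusted p = 0.767, median and upward test against a mean of -0.17 log2), of 9 thymocyte markers Lck and Dntt rose and Cd28 fell (adjusted p = 0.746, median of -0.06 log2 against a mean of 0.08 log2 and an upward test), and of 5 endothelial markers Flt1 fell (adjusted p = 0.767). Except for Lyz1 and for Dntt in clone 3, these marker genes lost their clone 3 call, and Dntt, Cd28 and Flt1 their clone 1 call, with the row as a block. Cd28 lost its clone 1 call in 13 of 18 alternative fits.

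Metabolic genes other than those of cholesterol showed single changes. Fatty acid oxidation genes rose in 8 and fell in 4 of 28 cases, 9 and 5 in the list alone (adjusted p = 0.0664), and Eci1, an isomerase of unsaturated fatty acids, fell by 3.65 and 2.30 log2. Of 21 genes of fatty acid synthesis 2 rose and 5 fell, 2 and 6 in the list alone (adjusted p = 0.767), with the desaturase gene Fads3 lower by 1.54 and 1.59 log2. Of 27 genes of serine, one-carbon and glutamine metabolism 1 rose and 6 fell (adjusted p = 0.0531), with the glutamine carrier Slc1a5 lower by 1.22 and 0.97 log2, a call that clone 3 lost with the row as a block. Of 25 glycolysis genes 3 rose and 6 fell (adjusted p = 0.767), with Aldoc up by 1.73 and 1.30 log2 and the lactate carrier Slc16a1 down by 0.66 and 0.77 log2. The pentose phosphate list had 2 of 11 genes lower, Rbks (-2.03 and -2.23 log2) and H6pd (-0.59 and -0.64 log2, calls lost with the row as a block), and 0 higher (adjusted p = 0.853). Of 24 genes of the TCA cycle 2 rose and 1 fell (adjusted p = 0.838). In oxidative phosphorylation 2 of 48 rose and 2 fell, 1 and 0 in the list alone (adjusted p = 0.955, median -0.04 and mean -0.01 log2 against an upward test). Of 15 prostaglandin genes 2 rose and 3 fell (adjusted p = 0.838), with the prostacyclin synthase gene Ptgis lower by 3.87 and 4.11 log2.

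Stress and growth control lists were not called either. Of 29 p53 targets 7 rose and 2 fell, 9 and 4 in the list alone (adjusted p = 0.0531). The stress cytokine gene Gdf15 rose by 1.79 and 1.70 log2 and the death gene Pmaip1 by 1.20 and 1.26 log2, whereas the death receptor gene Fas fell by 0.78 and 1.14 log2. With the mean of all probes Fas did not pass (adjusted p = 0.0529 and 0.06), since its other probe gave -0.17 and 0.11 log2. Of 27 apoptosis regulators 7 rose and 4 fell, 9 and 8 in the list alone (adjusted p = 0.853, median of -0.04 log2 against a mean of 0.05 log2 and an upward test), with the inhibitor gene Birc3 lower by 2.31 log2 in clone 1 and at least 4.76-fold in clone 3. Of 15 CDK inhibitors and senescence genes 4 rose and 2 fell (adjusted p = 0.696), with Cdkn2d up by 0.87 and 0.92 log2. Of 38 mitosis genes 1 rose and 5 fell (adjusted p = 0.0724), with the phosphatase gene Cdc25b lower by 1.78 log2 (SE 0.14) and 1.04 log2 (SE 0.16). Of 19 hypoxia genes 4 rose and 3 fell, 5 and 3 in the list alone (adjusted p = 0.853, median -0.09 and mean -0.06 log2 against an upward test), with the vasodilator gene Adm up by 1.86 and 1.72 log2. Of 25 glutathione and NRF2 targets 5 rose and 8 fell, 6 and 8 in the list alone (adjusted p = 0.955, mean -0.09 log2 against an upward test), with Gstm2 lower by 2.03 log2 in either clone. Among 26 genes of the TFII-I family and its chromosome 5 neighbourhood Gtf2ird2 and Cldn4 rose and Gtf2i, Lat2 and Rfc2 fell (adjusted p = 0.838), those of Lat2 and Rfc2 not passing in clone 3 with the row as a block.

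The last comparison asks where the clones differ from each other. Nts, which encodes the peptide neurotensin, was higher in clone 3 than in clone 1 by 2.13 log2 (SE 0.13, adjusted p = 0.0013), lying at 1.36 ± 0.16 in the controls (SD, n = 3), 0.64 ± 0.12 in clone 1 (SD, n = 3) and 2.77 ± 0.03 in clone 3 (SD, n = 2). The phospholipid synthesis gene Agpat4 was higher in clone 3 by 1.63 log2 (SE 0.14, adjusted p = 0.0086) and the claudin gene Cldn9 by 1.40 log2 (SE 0.13, adjusted p = 0.0088). Eci1 was higher by 1.35 log2 (SE 0.14, adjusted p = 0.017), the Y-linked family gene Sly by 1.42 log2 (SE 0.15, adjusted p = 0.017), and the antiviral synthetase gene Oas1a by 0.92 log2 (SE 0.11, adjusted p = 0.041). Loxl1, which cross-links elastin, was lower in clone 3 by 1.89 log2 (SE 0.14, adjusted p = 0.0031) and Xdh, the xanthine dehydrogenase gene, was lower by 1.73 log2 (SE 0.12, adjusted p = 0.0028). With the mean of all its probes Sly differed by 0.244 log2 and did not pass (adjusted p = 0.646). Limma's test passed 19 transcripts, 11 higher and 8 lower in clone 3, 2734 having an unadjusted p under the threshold. The balance turned to 25 higher and 37 lower with a variance trend, 2 and 5 without a filter, 13 and 48 without clone 3 replicate 1, and 9 and 26 without clone 3 replicate 2. Of 18 alternative fits Oas1a lost its call in 13, Eci1 in 9, Sly in 7 and Agpat4 and Cldn9 in 2 each. With the row as a block 13 passed, without Sly (1.36 log2), Eci1 (1.25 log2) and Oas1a (0.86 log2). Within row 2 alone, which holds 2 arrays of each clone, 0 transcripts passed in limma with 1552 under the unadjusted threshold, although Nts still differed by 2.10 log2 (adjusted p = 0.12) and Loxl1 by -1.99 log2 (adjusted p = 0.12).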

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

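The tests of the array row were chosen after the results were seen, whereas the tests by regrouping the arrays and by neighbouring genes were planned before the data were examined. The difference between the clones was singled out because arrays of the same genotype differed, in 19 transcripts. Of the genes named, Nts differed by 2.13 log2, Agpat4 by 1.63, Sly by 1.42, Cldn9 by 1.40, Eci1 by 1.35 and Oas1a by 0.92 log2, and Loxl1 by -1.89 and Xdh by -1.73 log2. Genes outside the naming rule, chosen after their values were seen, were Amot (3.03 log2, SE 0.16), Pcdh19 (-2.83 log2, SE 0.18), Nid1 (lower by at least 1.71-fold), Aoc1 (1.57 log2), Gm4836 (higher by at least 2.88-fold) and Gm16404 (1.12 log2). Col5a2 differed by 2.09 log2. Probes of Sly and of the Gm-numbered genes may read several copies of a family.

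Regrouping the 5 knock-in arrays into 3 and 2 gave 10 splits, of which only 1, the real one with 13 transcripts, called as many, and the highest other called 0. With 10 splits chance cannot be excluded. Recovery of simulated changes was not tested for this comparison. Different founding cells may explain the difference between the clones, which was not tested, and the count moved to 46 with normexp background and to 62 with a variance trend.

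Many transcripts changed alike in both clones. Regrouping all 8 arrays into 5 and 3 gave 56 splits, of which only 1, the real one with 8818 transcripts, called as many, and the highest other called 3, so chance is excluded only for arrays exchanged freely. The arrays come from 3 cell populations, too few to exclude chance differences between populations. All controls lie in row 1, so regroupings that respect the row exist only there, 4 in number, too few to exclude chance. Regrouping the 6 arrays of control and clone 1 gave 10 splits, of which only 1, the real one with 7926, called as many (highest other 0), too few to exclude chance by themselves. Gains or losses of chromosome segments could shift neighbouring genes together. To test this, each of 14713 genes was corrected by the median of its neighbours. Shared calls then numbered 3668 against 4181 before, which is 87.7%, and 3296 genes were called before and after with the same sign. Both counts belong to this test, and 4181 is not the count of shared calls with a symbol given above (4044). Neighbour medians ran from -0.46 to 0.54 log2 in clone 1 and from -0.67 to 0.47 log2 in clone 3. Some stretches of genes therefore shifted together, for a reason that was not tested. The counts argue against long segments as the main source. Segments with too few genes to move the median of the neighbours would not be seen and stay open.

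The array row could also produce such a count, since 3 of the 4 arrays in row 1 are controls. The clone 1 array in that row nevertheless followed the other clone 1 arrays with a slope of 0.968. The slope covers the 7662 transcripts called in clone 3 that had a value on every control and clone 1 array. With separate controls on the axes and all 25353 transcripts, the slope was 0.872 to 0.89. A control array in place of the clone 1 array gave -0.00483 to 0.00483 with separate controls and 0.0393 to 0.0557 with shared ones. A row effect predicts a slope under 0.5, so these values argue against the row as the main source, although they rest on 1 array, the one with low spike-in signals, and genes are not independent replicates. No test here separates the mutation from other differences between edited clones and the control population, such as the cell that founded each clone, shared steps of selection or time in culture. Each of these remains a possible explanation of the shared changes beside the mutation itself.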

How the results depend on the processing

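The fits within a single row, with a symbol only and without X and Y genes were added after the results were seen. Counts that moved by over 1.5 times are given here with some that moved less. Clone 1 against control moved from 7896 to 4349 with the array row as a block, 4714 at an adjusted p of 0.01, 2222 with at least 2-fold, 3597 in row 1 only and 5445 without a filter. Clone 3 against control moved from 7669 to 5103 without a filter, 2068 with the row block, 4325 at 0.01 and 2619 with at least 2-fold. Both clones moved from 5952 to 3938, 1967, 3483 and 1828 under the same alternatives, and to 4563 with symbols only. Knock-in against control moved from 8818 to 6896 without a filter, 4322 with the row block, 5549 at 0.01 and 2287 with at least 2-fold. Clone 3 against clone 1 moved from 19 to 46 with normexp, 7 without a filter, 62 with a variance trend, 11 at 0.01 and 0 in row 2 only. Stricter thresholds lower counts by construction, and in the other cases the cause was not tested. With the row block fold changes of the 5952 shared calls stayed close (slope 0.994 in clone 1 and 0.984 in clone 3). Median standard errors were 1.46 and 1.73 times as large. All controls lie in row 1, so in that fit clone 1 rests on its single row 1 array and clone 3 depends on it too. That array was also in the fit that chose the shared calls, so close slopes say little about the row. Leaving out each array in turn gave 6223 to 7926 for clone 1, 5150 to 7464 for clone 3, 4417 to 5509 for both, 6907 to 8724 for knock-in and 8 to 61 for clone 3 against clone 1 (8 without clone 1 replicate 2, 61 without clone 3 replicate 1, 35 without clone 3 replicate 2). With 1 array left in clone 3, that array is assumed to vary like the other groups. Called lists went from 5 to 14 with normexp, 13 without a filter, 8 with a variance trend, 30 with fry and 0 with an estimated correlation, and to 5 to 8 with an array left out (8 without control replicate 3). Gtf2i lay between -0.544 and -0.496 log2 with an array left out and lost its call with the row block (-0.501 log2). Gtf2ird1, which passed in no fit, turned positive in clone 3 with normexp (0.102 log2), median scaling (0.073), without control replicate 3 (0.026) and without clone 3 replicate 2 (0.083), and lay at -0.102 without clone 3 replicate 1. Evc turned positive in clone 1 with the mean of all probes (0.094 log2). Fry called glutathione and NRF2 targets (adjusted p = 0.00588), matrix proteases (adjusted p = 0.00164) and growth factors (adjusted p = 0.00399) lower where camera pointed up without a call. Fry tests a list by itself and camera tests it against the other genes, so their directions can differ. Why they did so here was not tested. Named genes kept call and sign in 3326 of 3397 fits for clone 1 and 3275 of 3397 for clone 3, but only in 111 of 144 for clone 3 against clone 1, and lists kept their side of the threshold without a reversed call in 793 of 861, among them 51 fits of 13 uncalled lists with the other sign and no call. No paired analysis was possible because replicate numbers follow the order of the records only. The planned block for slide or scan was not run, since there is 1 slide and 1 scan time. Signal over background limits folds, which are lower limits where a group had no array above it. These limits were taken from the main processing only, so they need not hold under another background correction.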

Other observations

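The scan of gene families and both tests on the X chromosome were chosen after the results were seen. Genes of the Rab family, small GTPases of membrane traffic and their effectors, were grouped by symbol. Rab29 rose from background at least 13.8-fold in clone 1 and 12.4-fold in clone 3, Rab42 by 1.68 and 1.93 log2, Rab3a, of exocytosis, by 1.57 and 1.58 log2 and Rab15 by 1.25 and 1.30 log2. The X-linked Rab39b fell to background, at least 9.75-fold and 9.35-fold. Of 63 members 24 rose in both clones, 38.1% against 15.5% of other genes with a symbol (Fisher's exact test, odds ratio 3.34, 95% interval 1.92 to 5.71, adjusted p = 0.00135), and 4 fell. With the row as a block 8 rose and 1 fell.

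Annexin genes, whose proteins bind membranes through calcium, were higher in 7 of 10 cases and lower in 0 (odds ratio 12.6, 95% interval 2.88 to 75.6, exact adjusted p = 0.0113). Anxa5 rose by 1.26 log2 (SE 0.14) and 1.38 log2 (SE 0.16), Anxa11 by 1.19 and 0.93 log2, Anxa6 by 1.01 and 1.07 log2 and Anxa1 by 0.54 and 0.53 log2. With the row as a block 3 rose. Solute carriers fell in 53 of 245 cases and rose in 32, a share lower of 21.6% against 12.1% (exact adjusted p = 0.00236). With the row as a block 23 fell and 12 rose, and with median scaling 36 fell and 31 rose. Olfactory receptor genes passed rarely, and their probes may be shared. Among 237 members 4 were higher (1.69% against 15.9% of other genes with a symbol, exact adjusted p = 2.31e-10). Only 2 were lower (0.844% against 12.5%, exact adjusted p = 5.57e-09). These were the only passing families among 160, in 320 tests, and genes of a family are not independent replicates.

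X-linked genes were frequent among fitted changes of at least 4-fold in both clones, with 34 of 472 (7.20%) against 375 of 14240 autosomal genes (2.63%), an odds ratio of 2.87 (95% interval 1.93 to 4.14, exact p = 3.92e-07). Examples chosen after their values were seen were Xist, the RNA that silences an X chromosome, which rose from background at least 8.54-fold and 6.10-fold, Adgrg2 at 3.58 and 3.37 log2, and Gpc3, a heparan sulfate proteoglycan gene, which fell to background, at least 7.34-fold and 7.03-fold. Gain or loss of a whole X chromosome could shift these genes together. The median of X-linked genes differed from that of autosomal genes by -0.097 log2 in clone 3 (95% interval -0.152 to -0.0454) and by -0.0493 log2 in clone 1 (95% interval -0.0828 to -0.00189). This argues against loss of an X or gain of an active one, but a gained X that is silenced would leave the median unchanged and stays open.

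Probes shared within multicopy families are another possible source. To test this, 131 X-linked genes were left out, those with a Gm number or a symbol stem that several X-linked genes share. The odds ratio was then 1.82 (95% interval 1.02 to 3.04, exact p = 0.0267, 16 of 341 genes). The rule went by symbol only, so it also removed Rab39b, Arhgap6 and Armcx2, and it was not applied to autosomal genes. Leaving out Slx as well gave 1.71 (95% interval 0.935 to 2.89), so these data cannot tell. Whether an X chromosome was silenced or reactivated in some cells was not tested and may underlie single genes.

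The first clone 1 array had a brightest spike-in signal of 2797 against 17164 to 30390 on the other arrays, with a spike-in slope of 0 in its header against 1.05 to 1.07. Its array weight was 0.998 in the fit of 3 groups, where the other arrays had 0.836 to 1.165, and 0.818 in the fit of 2 groups, where they had 0.580 to 1.239. On the second principal component (8.17% of the variance) it lay at 31.2, where the other arrays lay between -39.9 and 15.25.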
